A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

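Poly(A)-selected, strand-specific RNA libraries of budding yeast (Saccharomyces cerevisiae) were sequenced from 2 strains, in each of which the GAL1 promoter, active in galactose and shut off in glucose, drives 1 spliceosome gene. That gene is DIB1 in the Dib1 strain and SNU114 in the Snu114 strain. Each strain had 3 groups of 3 libraries, 18 in all: cells kept in galactose medium for 6 h, and cells grown in glucose medium for 4 h and for 8 h to deplete the protein. Per the labels, the submitters trimmed reads with Trimmomatic, aligned them with STAR to the sacCer3 genome, counted gene regions and intron regions separately with HTSeq, and normalised and tested with DESeq2; tool versions and the strand setting are not stated.

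The authors' deposited tables, 1 for genes and 1 for introns in each strain, hold for each library a normalised signal, the read count divided by 1 DESeq2 size factor per library. The authors' group comparisons are given in the same deposited tables as log2 fold changes and as adjusted p-values. In every library every value was a whole multiple of 1 step within a tolerance of 0.001, so whole read counts were recovered by dividing by that step. The gene tables list 6596 features, of which 6476 had a read in at least 1 library, and the intron tables list 284 host genes, each as 1 feature. The intron tables carry their own size factors, which remove any change shared by most introns. Intron values were therefore put back to reads and divided by the size factor of the gene table of the same library. The per-sample file headers name the replicate means as technical repeat averages, and the labels do not say whether the 3 replicates were separate cultures, so every p-value may measure technical spread alone. Coordinates come from the R64 annotation, the same assembly as sacCer3: 5914 of the 6596 gene identifiers and 281 of the 284 hosts were found in it. Features with no values in a table were not analysed here.

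The plan, written before the data were examined, named edgeR on counts if the files held counts and limma-trend on log2 values if they held normalised values. The latter was followed. Genes were tested with limma 3.58.1 in R 4.3.3 (limma-trend on log2 of the normalised value plus 1), with 1 fit of the 9 libraries of each strain and, for the difference between the strains' changes, 1 fit of all 18. Genes with no reads in a strain were left out, which left 6447 genes in each strain. Introns were tested in the same way as a level, on the scale of the gene table and for hosts with a mean of at least 5 intron reads. They were also tested as the log2 ratio of intron to gene reads, with 0.5 added to each and a mean of at least 20 gene reads. This ratio needs no scale between libraries. Gene reads can include intron reads, and 5 to 7 hosts per library had more intron than gene reads, so the ratio is not a fraction of unspliced molecules. p-values were adjusted by the Benjamini-Hochberg method over all features of a comparison and called at 0.05. The total intron share, all intron reads as a percent of all gene reads, was compared with exact two-sided permutation tests. For 3 libraries against 3 these cannot give a p under 0.1, and for both strains together, with groups exchanged within strains, not under 0.005. Exact binomial 95% intervals of the share of single libraries cover counting error only.

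A total of 34 gene lists, a list of strain markers with 2 tested genes, and 7 intron lists were fixed in advance. Each was described by its members past the threshold, by the number past it with p adjusted over the list alone, and, except the strain markers, by limma's camera test with the preset correlation of 0.01 and with an estimated correlation. Of 272 combinations of gene list and comparison, 113 passed with the preset correlation and 8 with the estimated one. The rule for named genes, also fixed in advance, took the target and marker genes, the 8 largest rises and falls of each comparison against galactose (5 for the others) among genes past the threshold, above a mean of 10 CPM and with groups that do not overlap, up to 2 members each way of each list, the largest intron changes, and the introns of ACT1, TUB1, TUB3, YRA1 and MUD1. Non-overlap of 3 libraries against 3 in a given direction or its reverse occurs by chance in 10% of genes.

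Depth was 17.1 to 58.6 M gene reads (M, mega) and 96655 to 1536697 intron reads per library. With changes added to simulated data of the same depth and spread, limma recovered 23.9%, 77.6% and 98.5% of genes changed 1.5-, 2- and 4-fold in the Dib1 strain and 22.4%, 80.6% and 100% in the Snu114 strain, with 5.00% and 4.93% false calls. For the difference between strains it recovered 8.96%, 47.8% and 97.0%, with 6.42% false calls. DESeq2 gave 13.1% to 13.8% false calls in the same tests. Fewer genes were changed in the simulated data than were called in the same real comparisons, and libraries were drawn independently. The shares of false calls need not hold for the real calls.

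Libraries with the same replicate number were checked for a shared effect. After group means were removed, the correlation across genes between libraries with the same number was 0.12 to 0.64 in the Dib1 strain and -0.16 to 0.62 in the Snu114 strain, and 8 of 9 libraries in each strain were closest to one of their own number. The labels do not state pairing, and the blocked fit was an alternative. Leaving out each library in turn, other pseudocounts (0.1 and 10), a minimum mean of 10, fits of only the 6 libraries compared, the replicate block, another intron scale and filter, other shares and the estimated camera correlation were alternatives fixed with the plan. Added after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the authors' own intron scale, and limma after removing each library's trend with gene length.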

Results

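RNA from the Dib1 and Snu114 strains was sequenced after 6 h in galactose, where the GAL1 promoter is on, and after 4 h and 8 h in glucose, where it is off. Each of the 6 groups had 3 libraries. Dib1 is a protein of the tri-snRNP that enters the spliceosome, and Snu114 is a GTPase of the U5 snRNP. The comparisons ask how reads over genes and over introns change when either is depleted. In the Dib1 strain the libraries held 17.9, 28.01 and 17.1 M (mega) gene reads at 4 h, 25.1, 25.1 and 17.8 M in galactose, and 58.6, 20.6 and 17.1 M at 8 h. In the Snu114 strain they held 25.4, 18.8 and 20.9 M at 4 h, 20.1, 41.9 and 23.2 M in galactose, and 21.9, 18.7 and 17.4 M at 8 h. Every depleted culture was also moved to another sugar, and no strain with both native promoters is among the samples. So depletion and the change of sugar cannot be separated in a comparison with galactose. The galactose libraries were also far above the native level of the driven gene. Beside the other strain, DIB1 mRNA was 95.5-fold and SNU114 mRNA 68.0-fold higher there. Loss of this excess cannot be separated from depletion or sugar in such a comparison either. From 4 h to 8 h both groups are in glucose, and depletion goes with longer time there. Normalised read counts are given as mean ± SD of 3 libraries and log2 changes as limma estimate ± SE.

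DIB1 mRNA (YPR082C, chromosome XVI, 704225 to 704656 in R64) in the Dib1 strain stood at 121968, 127214 and 117804 normalised counts in galactose, at 244, 249 and 263 after 4 h in glucose and at 265, 246 and 283 after 8 h. It fell by 8.92 ± 0.10 on the log2 scale at 4 h (limma adjusted p = 1.1e-11), and the 8 h estimate was -8.85 ± 0.10 (adjusted p = 1.2e-11). SNU114 mRNA (YKL173W, chromosome XI, 122517 to 125543) in the Snu114 strain stood at 161818, 159504 and 186566 in galactose, at 1210, 1247 and 1130 at 4 h and at 1180, 1252 and 1501 at 8 h. It fell by 7.14 ± 0.13 at 4 h (adjusted p = 1.1e-09), and the 8 h estimate was -7.02 ± 0.13 (adjusted p = 1.4e-09). From 4 h to 8 h the estimate was 0.07 ± 0.10 for DIB1 (adjusted p = 0.67) and 0.13 ± 0.13 for SNU114 (adjusted p = 0.72). The other strain keeps each gene's own promoter. Set beside it, DIB1 from the GAL1 promoter was 95.5-fold higher in galactose and stood at 25.7% and 24.9% of the native level at 4 h and 8 h. SNU114 was 68.0-fold higher in galactose and stood at 39.1% and 39.9% of the native level. GAL1 itself, which keeps the promoter at its own locus, changed by -10.16 ± 0.18 and -10.01 ± 0.18 at 4 h and 8 h in the Dib1 strain. Its change in the Snu114 strain was -9.82 ± 0.25 and -10.07 ± 0.25.

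**Figure D1:**
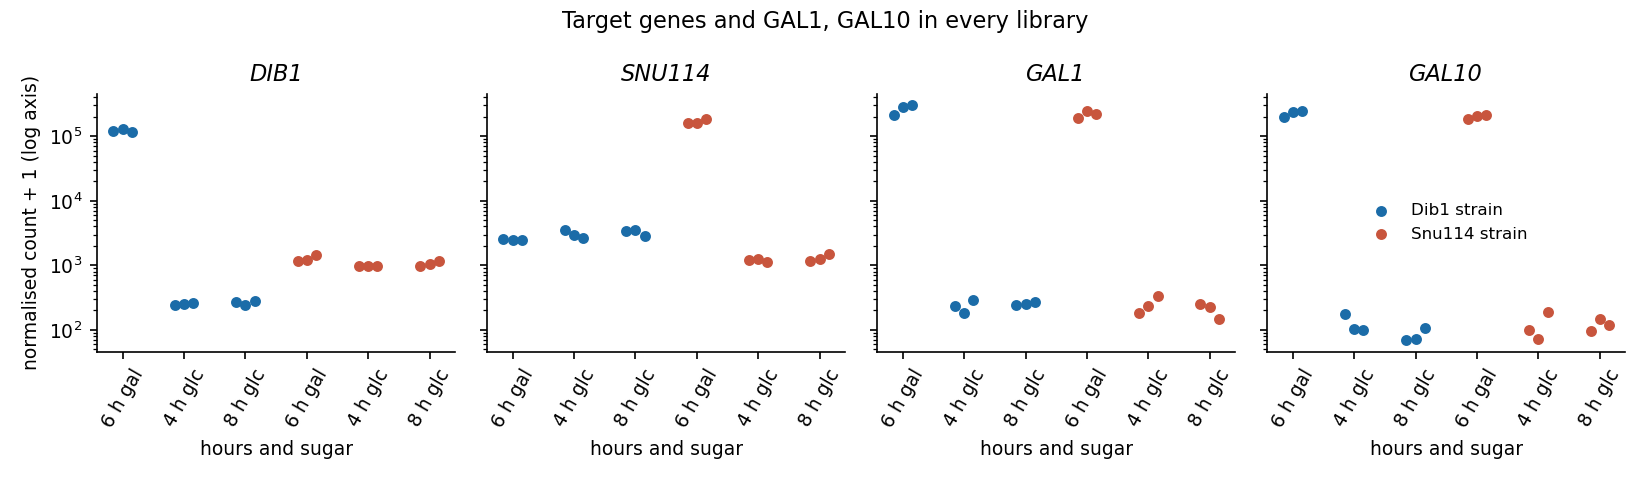
Normalised read count plus 1 on a log axis for DIB1, SNU114, GAL1 and GAL10 in each of the 18 libraries, 1 point per library, by hours and sugar (gal, galactose; glc, glucose). Each target is high only in its own strain in galactose, and in glucose it lies below the level of the other strain.

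LEU2, URA3 and MET17, which the labels give as deleted, had 0 reads in every library. HIS3, which the labels also give as a deletion allele, had 1191 to 2788 normalised counts. LYS2, given as deleted only in the Snu114 strain, had group means of 3185, 3138 and 3399 in the Dib1 strain (4 h, 6 h, 8 h) against 0 to 2.84 normalised counts in libraries of the Snu114 strain. The labels give both strains as mating type alpha. MF(ALPHA)1, the alpha-factor gene, had 71259 to 106892 normalised counts in Snu114 libraries and 9.60 to 62.9 in Dib1 libraries. MFA1, a gene for a-factor, had 2859 to 4862 in Dib1 libraries and 12.8 to 22.7 in Snu114 libraries, and HMRA1 had 1472 to 3158 against 0 to 1.14. STE2, the pheromone receptor of a cells, had 12594 to 22609 in Dib1 libraries and 106 to 190 in Snu114 libraries. The Dib1 libraries thus held transcripts of a cells and almost no MF(ALPHA)1, against their label of mating type alpha. Which of strain and mating type goes with any difference between the strains cannot be told from these libraries.

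Intron reads rose as a share of all gene reads in both strains, at 4 h in the Dib1 strain and by 8 h in the Snu114 strain. In the Dib1 strain the share went from 0.528% ± 0.0136 (SD, n = 3) in galactose to 1.77% ± 0.185 at 4 h and 2.57% ± 0.0470 at 8 h, 3.35 and 4.87 times the galactose share. In the Snu114 strain it was 0.592% ± 0.0510 in galactose, 0.535% ± 0.0225 at 4 h and 1.49% ± 0.149 at 8 h, 0.904 and 2.52 times the galactose share. In both Dib1 comparisons with galactose and at 8 h in the Snu114 strain, all 3 libraries of the higher group lay above all 3 of the other. This gives an exact two-sided permutation p = 0.1, the smallest these group sizes allow. For Snu114 at 4 h the exact p was 0.2. Over both strains the exact p was 0.005 at 8 h, the smallest possible, and 0.095 at 4 h. The change differed between the strains at 4 h by -1.30 percentage points (exact permutation p = 0.01), and at 8 h by -1.15 points (exact permutation p = 0.145). These permutations exchange groups within each strain. Their p-values therefore test against no change in either strain, not against equal changes, and do not decide whether the changes differ. The ratio at 4 h was lower with the introns of genes other than ribosomal protein genes alone, at 2.18 in the Dib1 strain.

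**Figure D2:**
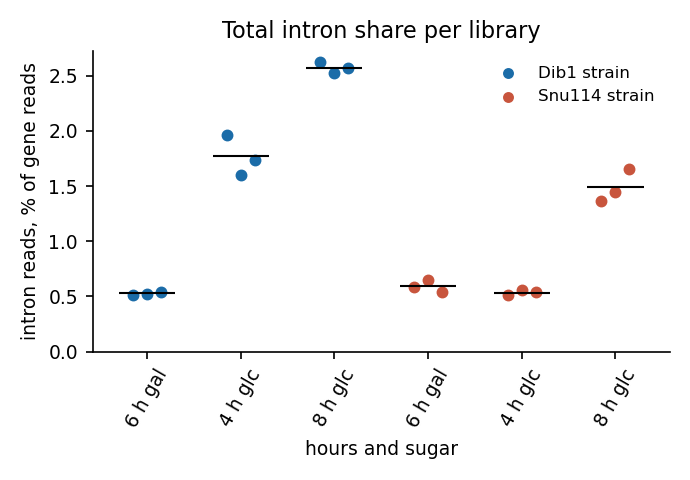
Intron reads as a percent of gene reads in each library (points) with group means (lines), by hours and sugar (gal, galactose; glc, glucose). The Snu114 libraries at 4 h lie between 0.510% and 0.554%, against 0.543% to 0.645% in galactose, while the Dib1 libraries at 4 h lie between 1.60% and 1.97%.

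In the Dib1 strain nearly all measured introns gained reads relative to their genes. The intron of the actin gene ACT1 (chromosome VI, 54378 to 54686) went from 0.791% ± 0.0730 of gene reads in galactose to 8.15% ± 2.59 at 4 h and 20.1% ± 1.73 at 8 h. That of TEF4, which encodes a translation elongation factor (chromosome XI, 283096 to 283421), went from 0.282% ± 0.0979 to 4.29% ± 0.879 and 12.6% ± 1.71. At 4 h the largest gains in the log2 ratio were TEF4 (3.96 ± 0.32), CGI121 (3.70 ± 0.23), NMD2 (3.69 ± 0.40) and NSP1 (3.53 ± 0.24). At 8 h they were TEF4 (5.54 ± 0.32), RPL19B (5.22 ± 0.32), RPS4B (4.90 ± 0.24), NMD2 (4.86 ± 0.40) and the actin-bundling gene SAC6 (4.78 ± 0.35). The intron of YRA1, an mRNA export gene whose intron is retained in growing cells, went from 16.7% ± 1.34 to 22.3% ± 1.07 and 37.9% ± 0.874, a smaller change (0.42 ± 0.12 and 1.18 ± 0.12). The TUB1 intron gained 0.94 ± 0.26 at 4 h and 2.21 ± 0.26 at 8 h, and that of MUD1, a U1 snRNP gene, 1.91 ± 0.23 and 2.37 ± 0.23. The ratio rose for 219 of 250 introns at 4 h (median 1.66) and for 230 at 8 h (median 2.58). From 4 h to 8 h it rose for 176 (median 0.87). With limma no ratio fell in these 3 comparisons at an adjusted p of 0.05.

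Ribosomal protein introns and other introns both moved. At 4 h the ratio rose for 86 of 89 introns of cytosolic ribosomal protein genes (86 adjusted over the list alone, median 1.89) and for 133 of 161 others (133 over the list alone, median 1.53). At 8 h these numbers were 89 of 89 (median 3.04) and 141 of 161 (median 2.40). Introns of snoRNA host genes rose in 7 of 8 at 4 h (median 2.28) and 8 of 8 at 8 h (median 3.11). Those of cytoskeleton and cell cycle genes in 15 of 16 at both times (medians 1.95 and 2.68). Introns of RNA processing genes rose in 12 and 13 of 13 (medians 1.91 and 2.37) and those of hosts with 2 introns in 6 and 7 of 7 (medians 1.60 and 2.52). The counts were the same over these lists alone. Introns of meiotic genes rose in 1 of 6 at each time, with medians of 0.19 and 0.59. As levels on the gene scale, 193 of 254 introns rose and 8 fell at 4 h (median 1.54), and 213 rose and 5 fell at 8 h (median 2.30). The authors' deposited table, where introns carry their own size factors, has 72 rises and 76 falls at 4 h, and 73 and 87 at 8 h. The limma fit on that scale gave 70 and 72 at 4 h and 73 and 82 at 8 h.

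In the Snu114 strain introns did not gain at 4 h, and gained broadly at 8 h. At 4 h the ratio fell for 42 of 249 introns and rose for 0 with limma (89 at an unadjusted p under 0.05, median -0.34), and edgeR on recovered reads gave 43 falls. RPL22A (chromosome XII, 263206 to 263594) went from 7.67% ± 0.604 to 2.17% ± 0.337 of gene reads (-1.83 ± 0.21, adjusted p = 0.0014). RPS23A went from 3.88% ± 0.996 to 1.30% ± 0.160 (-1.55 ± 0.29, adjusted p = 0.0073). ACT1 stood at 0.754% ± 0.134 and 0.565% ± 0.0822 (-0.41 ± 0.32, adjusted p = 0.42). Of 89 ribosomal protein introns 32 fell (48 adjusted over the list alone, median -0.65), and of 160 others 10 (5 over the list alone, median -0.19). The count of 42 was 78 with replicate number as a block, 24 without Snu114-4h replicate 1, 15 without replicate 2 and 14 without Snu114-6h replicate 1. As levels, 5 of 253 fell and 0 rose with limma, with 55 at an unadjusted p under 0.05; edgeR called 6 and DESeq2 24. They were RPL22A, RPS23A and, chosen after their values were seen, MRK1 (-3.30), YPR010C-A (-1.73) and UBC8 (-1.11). That count of 5 was 44 with the block, and 2, 3 and 3 without Snu114-4h replicates 1, 2 and 3 and 2 without Snu114-6h replicate 1 or 2.

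At 8 h in the Snu114 strain the ratio rose for 211 of 249 introns (median 1.57), and from 4 h to 8 h for 219 (median 1.97). TEF4 went from 0.196% ± 0.0591 to 4.55% ± 0.518 (4.56 ± 0.37) and ACT1 from 0.754% to 6.89% ± 2.81 (3.13 ± 0.32). CGI121 rose by 4.06 ± 0.31, RPL19B by 3.66 ± 0.33 and NSP1 by 3.38 ± 0.31. SAC6 rose by 3.37 ± 0.58 and NMD2 by 3.28 ± 0.45. MUD1 rose by 1.64 ± 0.24, while TUB1 had 0.68 ± 0.32 (adjusted p = 0.066). The ratio rose for 82 of 89 ribosomal protein introns (median 1.64), 129 of 160 others (median 1.52) and 7 of 8 snoRNA host introns (median 2.11). It also rose for 14 of 16 introns of cytoskeleton and cell cycle genes (median 1.76), 13 of 13 of RNA processing genes (median 1.64) and 6 of 7 hosts with 2 introns (median 1.92). The counts were the same over each of these lists alone. Among 6 introns of meiotic genes 1 rose (0 over the list alone, median 0.42). As levels 185 of 253 rose and 8 fell (median 1.39). In the authors' deposited table there were 65 rises and 62 falls, and on that scale the limma fit gave 60 and 60. At 4 h 0 of 249 ratios had risen in this strain, although GAL10 had already changed by -10.84 and HXT1 by 8.10. This argues against the move to glucose by itself as the cause of the intron gain in this strain. Depletion and longer time in glucose cannot be told apart.

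**Figure D3:**
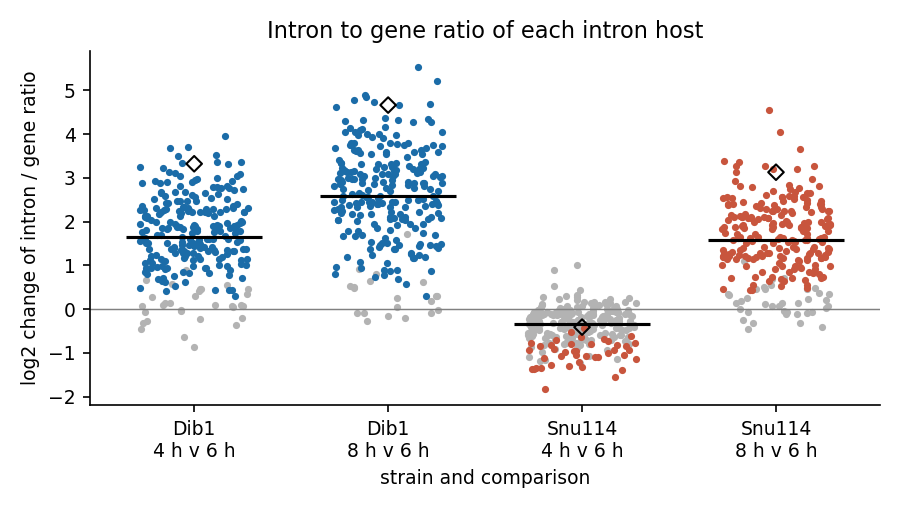
Log2 change of the intron to gene read ratio against galactose for each intron host (points, coloured when past an adjusted p of 0.05, grey otherwise), with the median (line) and ACT1 (diamond), by strain and comparison. The medians are 1.66, 2.58, -0.34 and 1.57 from left to right.

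The strains' intron changes were compared directly. At 4 h the difference between strains (Snu114 minus Dib1) in the log2 ratio was above 0 for 5.2% of 250 introns and below 0 past the threshold for 214 (median -1.93), with RPS4B at -4.70 ± 0.42, RPS4A at -4.56 ± 0.48, RPL31A at -4.44 ± 0.49 and ACT1 at -3.73 ± 0.39. At 8 h it was above 0 for 3.6% and below 0 past the threshold for 151 (median -0.99), with RPL22A at -2.42 ± 0.29, RPL16B at -2.39 ± 0.37 and RPL21A at -2.33 ± 0.34. That count was 62 without replicate 1 of every group and 67 without replicate 2, and other splits of the strain labels gave up to 162 calls. ACT1 at 8 h was at -1.53 ± 0.39 (adjusted p = 0.0044), and at -1.39 (adjusted p = 0.079) without replicate 1. The difference passed for 87 of 89 ribosomal protein introns and 127 of 161 others at 4 h (87 and 126 adjusted over each list alone), and for 85 and 66 at 8 h (86 and 54).

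After 4 h in glucose mRNAs for galactose use were lower in the Dib1 strain, and mRNAs for glucose transport were higher. All 11 measured genes of the GAL regulon fell (11 adjusted over the list alone, median -5.01, camera adjusted p = 0.0061 with an estimated correlation). GAL10 (YBR019C) changed by -10.86 ± 0.24 and the galactose permease gene GAL2 (YLR081W) by -10.72 ± 0.31. Of 8 genes of glucose-induced transport and sensing 6 rose (6 over the list alone, median 4.69, adjusted p = 0.10 with an estimated correlation). The low-affinity hexose transporter HXT1 (YHR094C) rose by 9.90 ± 0.37, from 7.05 to 7047 normalised counts, HXT3 (YDR345C) by 7.03 ± 0.38 and the glucose-responsive repressor MIG2 (YGL209W) by 5.03 ± 0.34. Of 24 glucose-repressed genes 20 fell (20 over the list alone, median -1.87, adjusted p = 0.032 with an estimated correlation). Among them were the lactate permease gene JEN1 (-4.16 ± 0.29) and FBP1, for a gluconeogenic enzyme (-2.68 ± 0.42). Respiratory chain genes fell in 34 of 38 (35 over the list alone, median -1.52, adjusted p = 0.10 with an estimated correlation), with QCR10 at -2.24 ± 0.23 and SDH2 at -2.17 ± 0.20. All 11 genes of the tricarboxylic acid cycle fell (11 over the list alone, median -1.10, adjusted p = 0.073 with an estimated correlation), with MDH1 at -1.80 ± 0.20.

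Nutrient and stress genes of the Dib1 strain also moved at 4 h. Of 20 methionine and sulfate genes 14 fell (18 over the list alone, median -1.31, adjusted p = 0.10 with an estimated correlation), with STR3, of methionine metabolism, at -2.50 ± 0.43. Of 14 iron regulon genes 7 fell (11 over the list alone, median -0.47, adjusted p = 0.032 with an estimated correlation), led by the cell wall mannoproteins FIT3 (-3.87 ± 0.25) and FIT2 (-3.31 ± 0.36). Of 38 genes of the induced environmental stress response 12 fell and 1 rose (14 over the list alone, median -0.49, adjusted p = 0.59 with an estimated correlation), with DDR2 at -2.16 ± 0.29. The peroxiredoxin gene AHP1 rose by 2.10 ± 0.19 and the oxidoreductase gene OYE3 fell by 3.38 ± 0.17. The cell cycle inhibitor FAR1 fell by 1.97 ± 0.14, and the arginine gene ARG1 changed by -2.21 ± 0.34. Among 89 ribosomal protein genes with an intron 5 rose and 2 fell (7 over the list alone, median 0.00, adjusted p = 0.92 with an estimated correlation): RPS9A rose by 0.86 ± 0.12 and RPS22B fell by 0.87 ± 0.16. In all 333 of 6447 genes rose and 646 fell with limma, and the authors' deposited table has 652 and 817. The total of 979 became 555, 419 and 621 without Dib1-6h replicates 1, 2 and 3, and 1479 with replicate number as a block.

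At 8 h in the Dib1 strain single genes of splicing factors, RNA decay and ribosome synthesis changed. PRP8, for the central U5 snRNP protein, rose by 2.05 ± 0.21, BRR2, for a U5 helicase, by 1.26 ± 0.12 and RSE1, for a U2 snRNP protein, by 1.26 ± 0.09, after 0.76, 0.41 and 0.39 at 4 h. PRP31, of the tri-snRNP, was at -0.61 ± 0.15, and LSM2 went from 2081 to 1037 normalised counts. Of 30 genes of the tri-snRNP, Sm and Lsm proteins 3 rose and 2 fell (5 adjusted over the list alone, median 0.14, adjusted p = 0.35 with an estimated correlation). The exonuclease gene XRN1 rose by 1.11 ± 0.11 and NMD2, of nonsense-mediated decay, by 0.95 ± 0.14. These are long genes, of 7242, 6492, 4086, 4587 and 3383 bp, and of 183 genes of at least 4 kb 133 rose (median 0.66). After each library's trend with gene length was removed the values were 1.12, 0.41, 0.77, 0.53 and 0.60, all past the threshold. UTP20, of ribosome biogenesis, went from 1.14 ± 0.16 to 0.19 (adjusted p = 0.27). DBP2, an RNA helicase gene, was at -1.66 ± 0.22 and NOG2, for a GTPase of ribosome assembly, at -1.12 ± 0.13, and both genes have an intron. Of 36 RNA decay genes 11 rose (11 adjusted over the list alone, median 0.19, adjusted p = 0.35 with an estimated correlation). Ribosomal protein genes with an intron fell in 38 of 89 and rose in 4 (45 over the list alone, median -0.54, adjusted p = 0.61 with an estimated correlation), with RPS22B at -1.87 ± 0.16, RPL2A at -1.66 ± 0.36 and RPS9A at 1.28 ± 0.12. Those without an intron fell in 8 of 48 (7 over the list alone, median -0.34, adjusted p = 0.65 with an estimated correlation), with RPL8A at -2.67 ± 0.25.

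Of the 38 stress response genes 13 rose and 4 fell at 8 h (19 over the list alone, median 0.54, adjusted p = 0.65 with an estimated correlation), with HSP42 at 2.20 ± 0.36 and SIP18 at -1.55. Of 24 heat shock factor targets 6 rose (6 over the list alone, median 0.50, adjusted p = 0.57 with an estimated correlation), the chaperone genes SSA2 by 1.20 ± 0.22 and KAR2 by 1.06 ± 0.16. Iron regulon genes rose in 8 of 14 and fell in 1 (11 over the list alone, median 0.61, adjusted p = 0.17 with an estimated correlation), ENB1 by 1.45 ± 0.18 and TIS11 by 1.38 ± 0.16. FIT3 fell by 2.14 ± 0.25. The glucan synthase GSC2 rose by 1.66 ± 0.10, while the profilin gene PFY1 was at -1.45 ± 0.21 and the cofilin gene COF1 at -1.41 ± 0.28. Of 45 Gcn4 targets 21 fell and 1 rose (22 over the list alone, median -0.47, adjusted p = 0.55 with an estimated correlation), with ARG1 at -2.61 ± 0.34 and MET6 at -2.28 ± 0.39. Of 20 methionine genes 15 fell (15 over the list alone, median -1.23, adjusted p = 0.21 with an estimated correlation), with MET2 at -2.29 ± 0.43. Of the GAL genes 11 of 11 fell again (11 over the list alone, median -4.28, adjusted p = 0.012 with an estimated correlation) and HXT1 rose by 8.46 ± 0.37, less than at 4 h (8 h against 4 h -1.43 ± 0.37, adjusted p = 0.032). Glucose-repressed genes fell in 17 of 24 (19 over the list alone, median -1.69), and the adjusted p with an estimated correlation, 0.032 at 4 h, was 0.16. Respiratory genes fell in 35 of 38 (37 over the list alone, median -1.35, adjusted p = 0.21 with an estimated correlation), with CYC1 at -3.13 ± 0.21. With limma 884 genes rose and 976 fell, against 1029 and 1142 in the authors' deposited table. The 1860 calls became 1236 and 1210 without Dib1-8h replicates 1 and 2.

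Between 4 h and 8 h in the Dib1 strain 556 genes rose and 373 fell. Of 183 genes of at least 4 kb 104 rose and 1 fell (median 0.54). The sporulation gene SPS100 rose by 3.52 ± 0.20, PHM7 by 3.06 ± 0.13, and FIT2 by 2.83 ± 0.36. GSC2 rose by 2.65 ± 0.10, the small heat shock gene HSP26 by 2.50 ± 0.22 and TIS11 by 2.06 ± 0.16. Iron regulon genes rose in 12 of 14 (12 adjusted over the list alone, median 1.26, adjusted p = 0.0087 with an estimated correlation) and stress response genes in 22 of 38 (26 over the list alone, median 0.89, adjusted p = 0.48 with an estimated correlation). The peptide transporter gene OPT2 was at -2.05 ± 0.23 and the histidine gene HIS1 at -1.66 ± 0.14. STE3, the a-factor receptor gene, was at -1.33 ± 0.18, from 169 to 66.6 normalised counts, while Snu114 groups had means of 5510 to 8956. Ribosomal protein genes with an intron fell in 31 of 89 and rose in 1 (41 over the list alone, median -0.59, adjusted p = 0.57 with an estimated correlation), with RPL31B at -1.38 ± 0.18 and RPL16A at -1.22 ± 0.13. The total of 929 was 322 and 355 without Dib1-8h replicates 1 and 2 and 474 in a fit of these 6 libraries alone. The authors' deposited table has 735 rises and 658 falls.

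In the Snu114 strain at 4 h in glucose GAL genes also fell and glucose-induced genes rose, and phosphate genes rose with them. In the strain difference at 4 h 0 of 11 GAL, 0 of 8 glucose-induced and 0 of 24 glucose-repressed genes passed (0, 2 and 0 over each list alone). This does not show that the changes were equal. All 11 GAL genes fell (11 adjusted over the list alone, median -5.17, adjusted p = 0.055 with an estimated correlation), with GAL10 at -10.84 ± 0.30. At the same time 7 of 8 genes of glucose-induced transport rose (8 over the list alone, median 4.11, adjusted p = 0.088 with an estimated correlation), HXT1 by 8.10 ± 0.56 and HXT3 by 6.83 ± 0.33. Phosphate regulon genes rose in 10 of 13 and fell in 1 (13 over the list alone, median 1.46, adjusted p = 0.10 with an estimated correlation). The phosphate transporter PHO84 (YML123C) rose by 4.49 ± 0.38, from 502 to 10316 normalised counts, and SPL2, of the same list, by 3.86 ± 0.29, while PHM8 fell by 0.93 ± 0.14. Of the same 13 genes 1 rose and 1 fell in the Dib1 strain at 4 h (PHO86 at 0.50 and PHO89 at -3.36), and 1 rose and 3 fell at 8 h. Of 24 glucose-repressed genes 14 fell (21 over the list alone, median -1.28, adjusted p = 0.14 with an estimated correlation), with JEN1 at -3.68 ± 0.32. Respiratory genes fell in 32 of 38 (36 over the list alone, median -0.98, adjusted p = 0.35 with an estimated correlation), with SDH2 at -1.63 ± 0.24. Stress response genes fell in 18 of 38 (21 over the list alone, median -0.83, adjusted p = 0.39 with an estimated correlation), with SIP18 at -3.13 ± 0.45 and DDR2 at -2.95 ± 0.37. Ribosomal protein genes with an intron rose in 11 of 89 (27 over the list alone, median 0.61, adjusted p = 0.42 with an estimated correlation). FIT3 was at -2.07 ± 0.15, FAR1 at -2.07 ± 0.16 and OYE3 at -3.37 ± 0.16. AHP1 rose by 1.79 ± 0.25, HIS4 by 1.35 ± 0.18 and EBP2, the nucleolar gene next to SNU114, by 1.71 ± 0.20. In all 244 genes rose and 495 fell, against 484 and 732 in the authors' deposited table. The total of 739 was 1497 with replicate number as a block, 331 and 327 without Snu114-4h replicates 1 and 2, and 391, 305 and 446 without Snu114-6h replicates 1, 2 and 3.

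At 8 h in the Snu114 strain GAL genes fell in 10 of 11 (11 adjusted over the list alone, median -4.08, adjusted p = 0.038 with an estimated correlation) and phosphate genes rose in 11 of 13 (12 over the list alone, median 1.46, adjusted p = 0.072 with an estimated correlation). PHO84 rose by 4.83 ± 0.38, SPL2 by 3.61 ± 0.29 and the phosphate symporter PHO89 by 3.35 ± 0.46. HXT1 rose by 7.65 ± 0.56, EBP2 by 1.88 ± 0.20, AHP1 by 1.59 ± 0.25 and TIS11 by 2.25 ± 0.29. CYC1 was at -1.89 ± 0.20, OYE3 at -2.97 ± 0.16, DDR2 at -2.31 ± 0.37 and FAR1 at -2.01 ± 0.16. MMP1, for an S-methylmethionine permease, was at -1.86 ± 0.16. Of 38 respiratory genes 33 fell (36 over the list alone, median -1.22, adjusted p = 0.26 with an estimated correlation). PRP8 rose by 0.98 ± 0.16 and RSE1 by 0.62 ± 0.10, and by 0.54 and 0.40 after the length trend was removed. BRR2 went from 0.63 ± 0.11 to 0.24 (adjusted p = 0.17) and XRN1 from 0.47 ± 0.13 to 0.21 (adjusted p = 0.36). With limma 211 genes rose and 368 fell, against 418 and 553 in the authors' deposited table. The 579 calls became 1112 with replicate number as a block, 312 and 357 without Snu114-8h replicates 1 and 2, and 367, 297 and 369 without Snu114-6h replicates 1, 2 and 3.

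From 4 h to 8 h in the Snu114 strain 80 genes rose and 43 fell. FIT2 rose by 2.65 ± 0.22 and FIT3 by 1.94 ± 0.15, and YBR255C-A fell by 1.53 ± 0.14. Iron regulon genes rose in 5 of 14 (7 adjusted over the list alone, median 0.47, adjusted p = 0.45 with an estimated correlation). Ribosomal protein genes with an intron fell in 11 of 89 and rose in 1 (56 over the list alone, median -0.72, adjusted p = 0.45 with an estimated correlation). The sum of both counts was 385 with replicate number as a block, 5 and 11 without Snu114-4h replicates 1 and 2, 31 and 6 without Snu114-8h replicates 1 and 2, and 18 in a fit of these 6 libraries alone. The authors' deposited table has 237 rises and 188 falls.

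**Figure D4:**
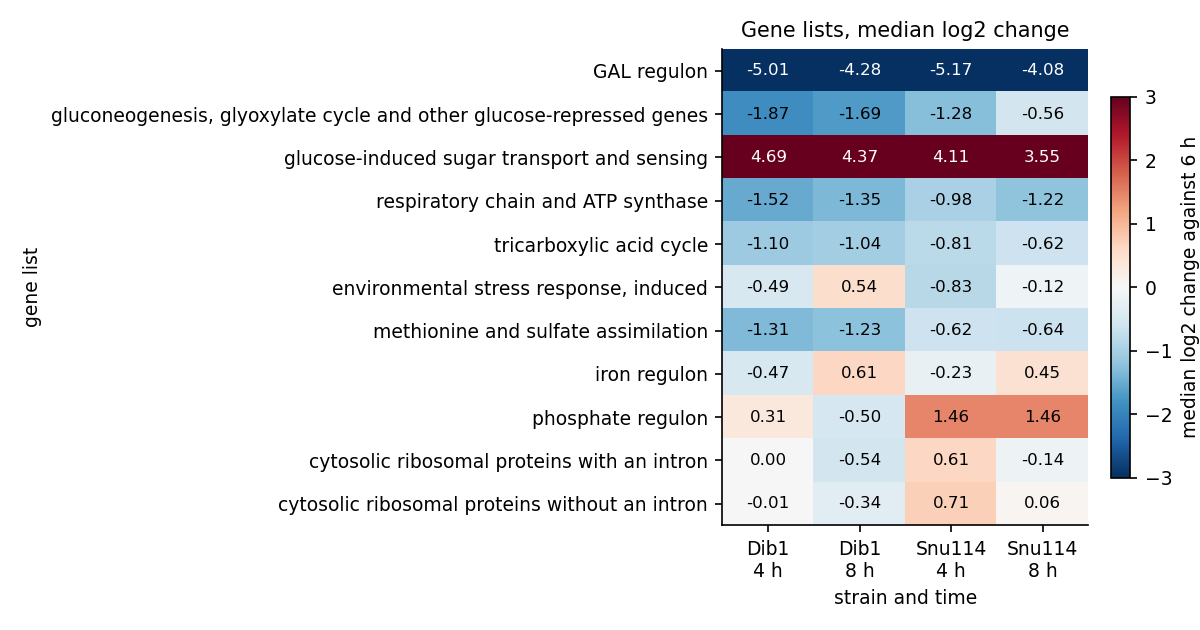
Median log2 change against galactose of 11 gene lists by strain and time in glucose; each cell prints its median and the colour scale stops at -3 and 3. GAL genes are lowest in all 4 columns, and the phosphate regulon is at 1.46 at both times in the Snu114 strain and at 0.31 and -0.50 in the Dib1 strain.

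The strains' changes were compared directly (Snu114 minus Dib1) to find responses that differed between the strains. Such a difference can come from the depleted gene, from another difference between the strains or from the galactose libraries. PHO84 had 502 normalised counts in Snu114 and 12669 in Dib1 galactose libraries. The median log2 strain difference of the 13 phosphate genes was -1.68 in galactose and -0.28 at 4 h. Apart from DIB1 (8.54 ± 0.15) and SNU114 (-7.43 ± 0.17), the phosphate genes PHO89 (4.65 ± 0.80) and PHO84 (4.07 ± 0.54), the alpha-factor gene MF(ALPHA)2 (4.05 ± 0.70) and SPL2 (3.99 ± 0.64) differed most at 4 h among the genes chosen by the rule. MF(ALPHA)2 had 0 to 6.60 normalised counts in Dib1 libraries, so part of its difference rests on counts near 0, and its change in the Snu114 strain alone was 2.66 ± 0.33. Of 13 listed phosphate genes 4 passed the threshold (10 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation). At 8 h PHO89 stood at 7.10 ± 0.80, PHO84 at 4.94 ± 0.54, SPS100 at -3.40 ± 0.36 and NCA3, a cell wall gene of the SUN family, at -2.93 ± 0.36. Then 10 phosphate genes were higher and 1 lower (13 over the list alone, median 2.57, adjusted p = 0.20 with an estimated correlation). At 4 h a-cell genes were lower in 2 of 6 (5 over the list alone, median -0.89, adjusted p = 0.029 with an estimated correlation). In Snu114 libraries these 6 genes had only 7.30 (AGA2) to 837 (STE6) normalised counts, so part of their difference rests on low counts. In Dib1 libraries they had 2804 (AGA2) to 27747 (MFA2). Haploid-specific genes were lower in 2 of 13 (8 over the list alone, median -0.50, adjusted p = 0.029 with an estimated correlation), in strains that also differed in the mating-type transcripts given above. With limma 22 genes were higher and 10 lower at 4 h, and 207 and 210 at 8 h. Of 183 genes of at least 4 kb 53 were lower and 0 higher at 8 h (median -0.42). The 32 calls at 4 h were 155 with replicate number as a block, and 2, 4 and 5 without replicates 1, 2 and 3 of every group, and of the genes named here only DIB1 and SNU114 passed each time. The 417 calls at 8 h were 799 with the block and 20, 13 and 143 without these replicates, and PHO89, PHO84, SPS100 and NCA3 passed each time. Across 6418 genes tested in both strains 81 rose and 321 fell in both at 4 h, against 12.7 and 49.7 expected by chance, and 5 changed in opposite directions, against 50.2 expected. At 8 h the numbers were 154, 276 and 11, with 29.1, 55.8 and 82.7 expected.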

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

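The tests of library scaling, of SNU114 mRNA left at 4 h, of the ratio in galactose, of the phosphate genes in galactose and of splits that keep same-number libraries together were chosen after the result was seen. The tests for genomic DNA and for 1 outlying library, and the other splits of the libraries, were set beforehand.

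The changes of the strains differed from each other in 5 summary results, those of genes and of intron ratios by a test of the difference itself. With limma 32 genes differed at 4 h and 417 at 8 h, and the intron to gene ratio differed for 214 introns at 4 h and 151 at 8 h. The total intron share differed at 4 h by -1.30 percentage points (exact permutation p = 0.01). That p tests against no change in either strain, not against equal changes. For the genes, 1 of 100 splits of the strain labels within times, the real one, gave as many calls at 4 h (highest other 18), and 1 of 100 at 8 h (highest other 4). For the 214 introns at 4 h it was 1 of 100 (highest other 165). These splits part libraries with the same number, which deviated together in the Dib1 strain (correlation 0.12 to 0.64). In the Snu114 strain the correlation was -0.16 to 0.62. In each strain 8 of 9 libraries were closest to one of their own number. Splits that keep same-number libraries together number 10, too few for a share under 0.05. The real split among these gave 34 genes at 4 h and 378 at 8 h, not the 32 and 417 of the reported fit. The highest other gave 2 genes at either time and 0 introns. For the 151 introns at 8 h 5 of the 100 splits gave as many, the highest 162, and chance cannot be excluded. Each of these 4 other splits exchanged 1 library of the 8 h set per strain. With replicate number as a block 155 and 799 genes differed at 4 h and 8 h. The 32 genes became 2, 4 and 5 without replicates 1, 2 and 3 of every group, the 417 genes 20, 13 and 143, and the 151 introns 62 and 67 without replicates 1 and 2.

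Within a strain the 6 libraries of a comparison make 10 splits, too few for a share under 0.05, and in each of these comparisons 1 split, the real one, gave as many calls. The other splits mix the groups, which puts a large group difference into the spread within groups and leaves few calls. Their low counts therefore do not decide whether chance gave the real ones. In the Dib1 strain the real split gave 979 genes at 4 h, 1860 at 8 h and 929 from 4 h to 8 h, and the highest other gave 0. For the Snu114 strain it gave 739 genes at 4 h and 80 rises with 43 falls from 4 h to 8 h (highest other 0), and 579 at 8 h (highest other 1). For intron levels the real split gave 201 and 218 in the Dib1 strain and 5 and 193 in the Snu114 strain, at 4 h and 8 h, and the highest other gave 0. For the intron to gene ratio it gave 219, 230 and 176 in the Dib1 strain (4 h, 8 h, 8 h against 4 h) and 42, 211 and 219 in the Snu114 strain, and the highest other gave 0. Among the 4 splits of each Dib1 comparison that part every same-number pair, as the real one does, the highest other gave 0 too. The libraries whose removal moves these counts are named with each comparison of the report.

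As levels, which depend on a scale between libraries, 193 introns rose and 8 fell at 4 h in the Dib1 strain, and 5 fell in the Snu114 strain. That scale as the cause is argued against by the intron to gene ratio, which needs none and had a median strain difference of -1.93 (quartiles -2.90 and -1.25), and different controls by the ratio in galactose, where the median difference was 0.01. Genomic DNA would add reads evenly along the genome, but 64.3% of 5812 annotated genes had fewer reads per kb in the Dib1 libraries at 4 h than the 2435 that the median of 237 introns gained. More SNU114 mRNA at 4 h than at 8 h is argued against by its change of 0.13 between these times (-0.13 to 0.38, estimate ± 2 SE). Which gene was depleted, the 39.1% of native SNU114 mRNA left against 25.7% for DIB1, a slower loss of Snu114 protein, and the other differences between the strains, mating-type transcripts among them, stay open, untested.

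Of 13 phosphate regulon genes 10 and 11 rose at 4 h and 8 h in the Snu114 strain, against 1 and 1 in the Dib1 strain, where 1 and 3 fell. An outlying library is argued against at 8 h, since 8 of 13 listed genes still rose without Snu114-8h replicate 1 and 9 to 11 with any other Snu114 library of 8 h or galactose left out. A candidate explanation is that the galactose cultures differed: in galactose the listed genes were lower in the Snu114 than in the Dib1 strain (median -1.68, quartiles -3.35 and -0.80), against -0.28 at 4 h and 0.71 at 8 h. PHO84 had 502 normalised counts in Snu114 galactose libraries and 12669 in Dib1 galactose libraries, and 10316 and 15900 at 4 h. A difference in the media and one between the strains would give the same values, and which gene was depleted stays open, untested, for the remainder at 8 h.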

How the results depend on the processing

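Tests of edgeR and DESeq2 on recovered reads, the authors' own intron scale and the removal of the trend with gene length were chosen after seeing the data, and no alternative fixed with the plan was left out. Of the values of summary results under an alternative, 255 kept their direction and stayed within 1.5 times the count, or within 1 SD, and 64 did not. The ratio calls stayed within 212 to 226 (Dib1 4 h), 222 to 234 (Dib1 8 h), 147 to 198 (Dib1 8 h against 4 h), 200 to 221 (Snu114 8 h), 208 to 228 (Snu114 8 h against 4 h) and 196 to 217 (strain difference at 4 h) under every alternative run. Intron levels at 4 h and 8 h in the Dib1 strain stayed at 142 to 211 and 155 to 223 calls, but scales made from the introns themselves split them evenly into rises and falls, since they remove a shared change. For the same reason Snu114 at 8 h gave 119 with TMM from the introns and 120 on the authors' own scale, of which 55 and 60 rose, in place of 193. DESeq2 called more genes: 1514 (Dib1 4 h), 1427 (Dib1 8 h against 4 h), 1246, 976 and 437 (Snu114 4 h, 8 h, 8 h against 4 h), 157 and 698 (strain difference at 4 h and 8 h), and 24 intron levels for Snu114 at 4 h. In simulated data, with fewer changed genes and independent libraries, 13.1% to 13.8% of its calls were false, a share that need not hold here. The replicate block gave 1479 (Dib1 4 h), 1497, 1112 and 385 (Snu114), 155 and 799 (strain difference), and for Snu114 at 4 h 44 intron levels and 78 ratios. The cause was not tested. Fits of only the 6 libraries compared gave 509 (Dib1 4 h), 474 (Dib1 8 h against 4 h) and 18 (Snu114 8 h against 4 h), with fewer libraries to estimate the spread. With 1 library left out, the gene counts ran from 419 (without Dib1-6h replicate 2) to 1373 (without Dib1-4h replicate 2) for Dib1 4 h, 1210 to 1545 (without Dib1-8h replicates 2 and 3) for 8 h, and 322 (without Dib1-8h replicate 1) to 1320 (without Dib1-4h replicate 1) for 8 h against 4 h. For Snu114 they ran from 305 (without Snu114-6h replicate 2) to 719 (without Snu114-4h replicate 3) at 4 h, 297 (without Snu114-6h replicate 2) to 743 (without Snu114-8h replicate 3) at 8 h, and 5 to 141 (without Snu114-4h replicates 1 and 3) for 8 h against 4 h. The strain difference ran from 2 to 5 (without replicates 1 and 3 of every group) at 4 h, and 13 to 143 (without replicates 2 and 3) at 8 h. For Snu114 at 4 h intron levels ran from 2 (without Snu114-4h replicate 1) to 7 (without Snu114-6h replicate 3) and ratios from 14 to 40 (without Snu114-6h replicates 1 and 3). The ratio difference at 8 h ran from 62 to 130 (without replicates 1 and 3 of every group). Fewer libraries lower the power, and the cause of the rises was not tested. The total intron share of Dib1 became 2.18 times that in galactose at 4 h and 4.07 times at 8 h without ribosomal protein genes, and 5.18 times at 8 h without the 5 introns with most reads. With host gene reads as denominator it became 6.15 times for Dib1 at 8 h and 0.691 for Snu114 at 4 h. The cause was not tested. Of 113 calls of gene lists 8 were past the threshold with an estimated correlation, and the cause was not tested. Without the length trend the gene counts were, in the order Dib1, Snu114 (4 h, 8 h, 8 h against 4 h each) and strain difference (4 h, 8 h), 920, 1723, 848, 789, 562, 136, 39 and 376, and 828, 1499, 727, 678, 492, 112, 28 and 326 of these genes were the same. LYS2 and IQG1 in the Dib1 strain at 8 h reversed, from 0.12 to -0.39 and from 0.52 to -0.044, the trend being what was removed. Of 503 named gene results 280, and of 91 named intron results 75, kept direction and side of the threshold in every alternative. Depth and 3 libraries limit small changes: in simulated data the ratio test found 20%, 50% and 100% of introns changed 1.5-, 2- and 4-fold in the Dib1 strain, 5%, 25% and 95% in the Snu114 strain, and for the strain difference 0%, 15% and 50%.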

Other observations

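The 3 tests on long genes, the host test with the length trend removed, its minimum mean of 100 and the hypergeometric p for neighbouring genes were chosen after the result was seen. The other tests on hosts, introns and neighbours were set beforehand.

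Cell cycle and differentiation genes were among the further fixed lists. In the Dib1 strain at 4 h 4 of 16 G1/S genes rose (5 adjusted over the list alone, median 0.29, adjusted p = 0.33 with an estimated correlation), as did 4 of 15 G2/M genes (6 over the list alone, median 0.40, adjusted p = 0.33). Of 17 meiosis and sporulation genes 5 fell (5 over the list alone, median -0.39, adjusted p = 0.15). At 8 h 6 of these fell and 2 rose (9 over the list alone, median -0.50, adjusted p = 0.28), with SPS4 at -2.74 ± 0.20 and the cohesin gene REC8 at -1.49 ± 0.18. REC8 was also at -1.49 ± 0.16 in the Snu114 strain at 4 h. The mating-type switch endonuclease gene HO was at -1.91 ± 0.27 in the Dib1 strain at 8 h, while the cyclin gene PCL1 rose by 1.17 ± 0.27. TUB3 rose by 0.54 ± 0.10 in the Dib1 strain at 8 h and by 0.62 ± 0.10 in the Snu114 strain at 4 h, where the alpha-factor gene MF(ALPHA)2 rose by 2.66 ± 0.33 and PRM1, of cell fusion, was at -1.01 ± 0.17.

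Messengers of splicing factors moved little as lists. At 8 h in the Dib1 strain 3 of 30 genes of the tri-snRNP, Sm and Lsm proteins rose and 2 fell (5 over the list alone, median 0.14, adjusted p = 0.35 with an estimated correlation), and 3 of 23 of the U1 and U2 snRNPs rose (3 over the list alone, median 0.13, adjusted p = 0.34). Of 31 Prp19 complex and catalytic-stage genes 1 rose (1 over the list alone, median 0.10, adjusted p = 0.80). These lists had 2 of 30, 1 of 23 and 1 of 31 rises at 8 h in the Snu114 strain (2, 1 and 0 over each list alone, medians 0.06, 0.05 and 0.08).

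Long genes gained at 8 h. Of 183 genes of at least 4 kb 133 rose and 6 fell in the Dib1 strain (median 0.66) and 44 rose and 2 fell in the Snu114 strain (median 0.28). A single library is argued against, since 6 of 6 libraries at 8 h stood above every galactose library of their strain, and intron reads are argued against by the long genes without an intron, with a median of 0.66 (0.55 to 0.77) in the Dib1 strain. RNA that was less degraded at 8 h cannot be told apart from a change of the cells: both predict the gain of 0.77 over genes under 1 kb, and no measure of RNA integrity was used here.

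Genes with an intron outside the ribosomal protein genes may lose mRNA when their splicing fails. At 8 h their median log2 change lay below that of other genes by -0.30 in the Dib1 strain (158 against 5115 genes) and -0.27 in the Snu114 strain (156 against 5097). Without the length trend the differences were -0.24 and -0.23. The permutation p was 1e-05 in each, the smallest these permutations can give, and runs across genes, which are not independent replicates. Since the sugar changed too, this does not separate splicing from the response to glucose.

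Features of introns were set against the ratio change at 8 h, across introns, which are not independent replicates. Introns with little unspliced RNA in galactose in the other strain changed more, with Spearman's rho of -0.63 (Dib1) and -0.69 (Snu114), permutation p = 1e-05 each, the smallest possible. Among introns under 10% in galactose rho was -0.35 and -0.48, and a ratio that starts high has less room to rise, which could give part of the relation. Longer introns did not change more by the bound of 0.2 set for rho: it was 0.17 (permutation p = 0.0072) and -0.026 (p = 0.69). The 58 introns with a first hexamer other than GTATGT changed less than the 179 with it. The medians differed by -0.49 (permutation p = 0.022) and -0.38 (p = 0.033). Outside the ribosomal protein genes the medians were 1.52 against 2.50 and 1.19 against 1.64. The hexamer groups were not compared at the same galactose ratio. An effect of the 5′ splice site therefore cannot be told from a difference in the starting ratio. Adjusted over these 6 relations the p-values were 3e-05 for both baselines, 0.014 and 0.69 for length, and 0.033 and 0.040 for the hexamer.

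Of the 4 genes next to DIB1 and SNU114, 2 differed between the strains' changes (exact hypergeometric p = 0.024 against 428 of 6476 genes), so the altered loci may act on their neighbours. By strand and the order of systematic names, these 2, EBP2 and GRS2, lie past the 3′ end of the target. MDM36 and TPO5, on the side of the inserted promoter, did not pass (limma adjusted p = 0.22 and 0.086 at 8 h). How a neighbour came to differ was not tested. EBP2, next to SNU114, differed by 1.44 at 4 h and 1.75 at 8 h, with 3625 normalised counts in Snu114 and 12860 in Dib1 galactose libraries. GRS2, next to DIB1, differed by 1.78 at 8 h, with 4597 in Dib1 and 2186 in Snu114 galactose libraries. Another difference between the strains near these loci was not tested.

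A pair of libraries stood apart from their groups. The SD of the log2 deviations from the group mean was 0.402 in Dib1-4h replicate 1 and 0.375 in Snu114-8h replicate 3. Without the former 1029 genes passed for Dib1 at 4 h and 1320 for 8 h against 4 h, in place of 979 and 929. Without the latter 743 passed for Snu114 at 8 h, in place of 579. Replicates 1 and 2 at 8 h were unusually alike. The chi-square per gene between them was 12.7 in the Dib1 strain and 13.2 in the Snu114 strain. Other pairs of libraries within a group had 56.2 to 348.5. The 743 calls thus rest on 2 libraries at 8 h that may not be independent. Why these pairs were alike was not tested.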
